A study of Homo sapiens with 16 samples.

How the data were processed

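Gene expression was measured by sequencing of poly-adenylated RNA from 16 samples of WA01 human embryonic stem cells induced toward neural crest with 3 µM CHIR99021. The labels give 4 genotypes, 2 differentiation days (day 3, called pre-neural crest, and day 5, called neural crest) and 2 replicates for each of the 8 groups. The genotypes are 2 isogenic wild-type lines, isoWT1 and isoWT2, and 2 lines edited at the translational start of FOXB1 with a single guide RNA, called Het and KO. Cells were plated at 20000 per cm2, and the ROCK inhibitor Y-27632 (10 µM) was present at the start.

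The submitters' processing notes name TopHat2 2.1.1 for alignment to hg19 and Cuffdiff 2.2.1 for quantification and testing. Library filters and the annotation version are not given in the sources used here. The authors' deposited table holds 349260 lines, 1 for each of 23284 genes in each of 15 comparisons of 6 groups. The deposited values are FPKM per gene and group, so no value per library, count or depth was at hand. The deposited fold changes are on the log2 scale, the deposited test score is the natural logarithm of the fold change over its standard error, and the deposited p-value and q-value belong to that score. The smallest deposited p-value is 5e-05, and the deposited q-value equals a Benjamini-Hochberg adjustment over the 222234 tests of all 15 comparisons to within 5.28e-07.

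The table has a single wild-type group per day, while the labels have 4 wild-type libraries per day. Which of them entered that group is not stated in it. The choice made before the data were examined was to call a gene only when it differed from both wild-type lines. That could not be done, so the comparison with the single wild-type group took its place. The group named HOMO in the table was read as the KO line. Of the 15 comparisons, 9 were used. They were KO and Het against wild type at each day, KO against Het at each day, and day 5 against day 3 within wild type, Het and KO.

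A gene was called where its q-value in the authors' deposited table was below 0.05, with no minimum fold change. Expressed genes were those with at least 1 FPKM in both groups compared. Fold changes were computed from the group FPKM without a pseudocount, and genes at 0 in a group entered with no fold. The standard error (SE) of each log2 change was taken from the deposited fold change and test score. The implied variances of comparisons were sums of 1 variance per group, with a median relative error of 1.9e-06 over 14658 genes, which gave an SE for each group. The deposited p-values were smaller than a normal reading of the test scores gives, so an alternative scaled the SE by that ratio.

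The change from day 3 to day 5 in each edited line was compared with that in wild type as a difference of log2 changes over its implied SE, with a 2-sided normal p and Benjamini-Hochberg adjustment over genes. This test was checked on simulated data from 14658 genes. At log2 sizes of 1, 2, 4 and 6 it recovered 0%, 10%, 82% and 92% of the changed genes with 0 false calls, and with scaled SE 16%, 80%, 94% and 98% with 8 false calls. The simulated noise was the implied SE times 0.55, the ratio of the wild-type time course. Few false calls with the full SE were therefore fixed in advance. That ratio was 0.71 in Het and 0.72 in KO, and no GC or chromosome trend was simulated, so false calls in the data are not measured by this.

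The 21 gene lists were fixed before the data were examined. Some share members, so their results are not independent. PAX3, PAX7 and TFAP2A are in the neural plate border and crest specifier lists, and MSX1 and MSX2 in the border and BMP lists. BAMBI is in the WNT and BMP lists, GBX2 in the border and midbrain lists, and other pairs of lists overlap as well. Each list's median change used log2 of FPKM plus 0.1 and was placed as a percentile among 10000 lists drawn at random, each member replaced by a gene within 100 ranks of mean expression. The median covers every member with a level above 0 in either group, also members not tested. The counts of rises and falls cover tested members alone. Calls within a list were also made with Benjamini-Hochberg adjustment over the list alone. Percentiles describe the groups at hand and are no test over replicates. Genes shared by the KO and Het calls were counted beside the number that independent lists of those sizes would share, and beside 100 simulations of unchanged groups compared with the same wild-type group, drawn from the implied variances scaled to the spread of the deposited p-values. Small RNA features and genes with an implied variance above 1 (298 at day 3 and 287 at day 5) were left out of these simulations and of the covariance after it was seen with all genes.

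The genes named were FOXB1, then for each comparison the 10 called genes with the largest rise and the 10 with the largest fall among genes with at least 1 FPKM in a group compared, and up to 4 called members of each list. For the time course they were list members called in the same direction in wild type, Het and KO, and for differences in timing up to 10 of the largest either way. Genes outside this rule are said to be chosen after their values were seen. The 92 entries of several symbols, the 30 genes whose FPKM differed between comparisons and the 1639 small RNA features were left out of the named genes. In all, 5979 genes (25.7%) share a locus with another gene in the table. The libraries are not stated to be stranded, so their FPKM can hold reads of the other gene. Among the genes named, these are TFAP2A, PAX3, TNIK, PROC, FOXH1, PAX5, ACTA2, TAGLN, CXCL11, ZFHX4, SOX2, SLC2A1, BBC3, FOXM1, MAML2, NR2F2, NTRK3, MAMDC2 and TRIM61. Y-linked genes and XIST are not reported.

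Transcript GC content came from GENCODE 29, an annotation of another genome build, joined by gene symbol for about 89% of expressed genes. Fold changes were centred within 20 bins of GC content, and calls were remade at the size of the test score that gives the deposited number of calls. Chromosome medians used expressed genes, 20 Mb windows with at least 20 genes, and chromosome 1 divided at 125 Mb. These steps, and a set of genes with at least 5 FPKM in KO at day 5 and under 0.05 of that level in both Het groups, were chosen after the data were seen. Other alternatives were a q-value of 0.01, adjustment within each comparison, a log2 change of at least 1, pseudocounts of 0.01 and 1, an FPKM minimum of 1, centring, and a doubled SE. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.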

Results

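RNA from human neural crest induction was sequenced at day 3 and day 5 in 4 genotypes, with 2 replicates in each of the 8 groups. The genotypes were 2 isogenic wild-type lines, a FOXB1 Het line and a FOXB1 KO line. The study asked how loss of the FOXB1 protein, a forkhead transcription factor, alters gene expression as the cells pass from pre-neural crest to neural crest. The authors' deposited table has 1 wild-type group per day, without stating which of the wild-type libraries entered it. It gives 1 FPKM per gene and group, so replicate spread is known only through its test scores. Depth per sample is unknown. Between 13100 and 13562 genes reached at least 1 FPKM per group. The median standard error relative to the level was 0.32 to 0.34 at 1 to 3 FPKM and 0.20 to 0.21 at 100 FPKM or more. Log2 changes below are given with the SE that the deposited test scores imply.

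FOXB1 itself (chromosome 15, 60296421 to 60298142 in hg19) stood at 18.3 FPKM in wild type, 7.73 in Het and 15.5 in KO at day 3. At day 5 it stood at 5.51, 4.47 and 1.86 FPKM. FOXB1 fell in Het at day 3 (log2 change -1.25, SE 0.58) and in KO at day 5 (-1.56, SE 0.69). Its changes in KO at day 3 (-0.24, SE 0.56) and in Het at day 5 (-0.30, SE 0.54) were not called. An edit at the translational start need not lower the messenger RNA, so these levels are no measure of the protein.

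**Figure D1:**
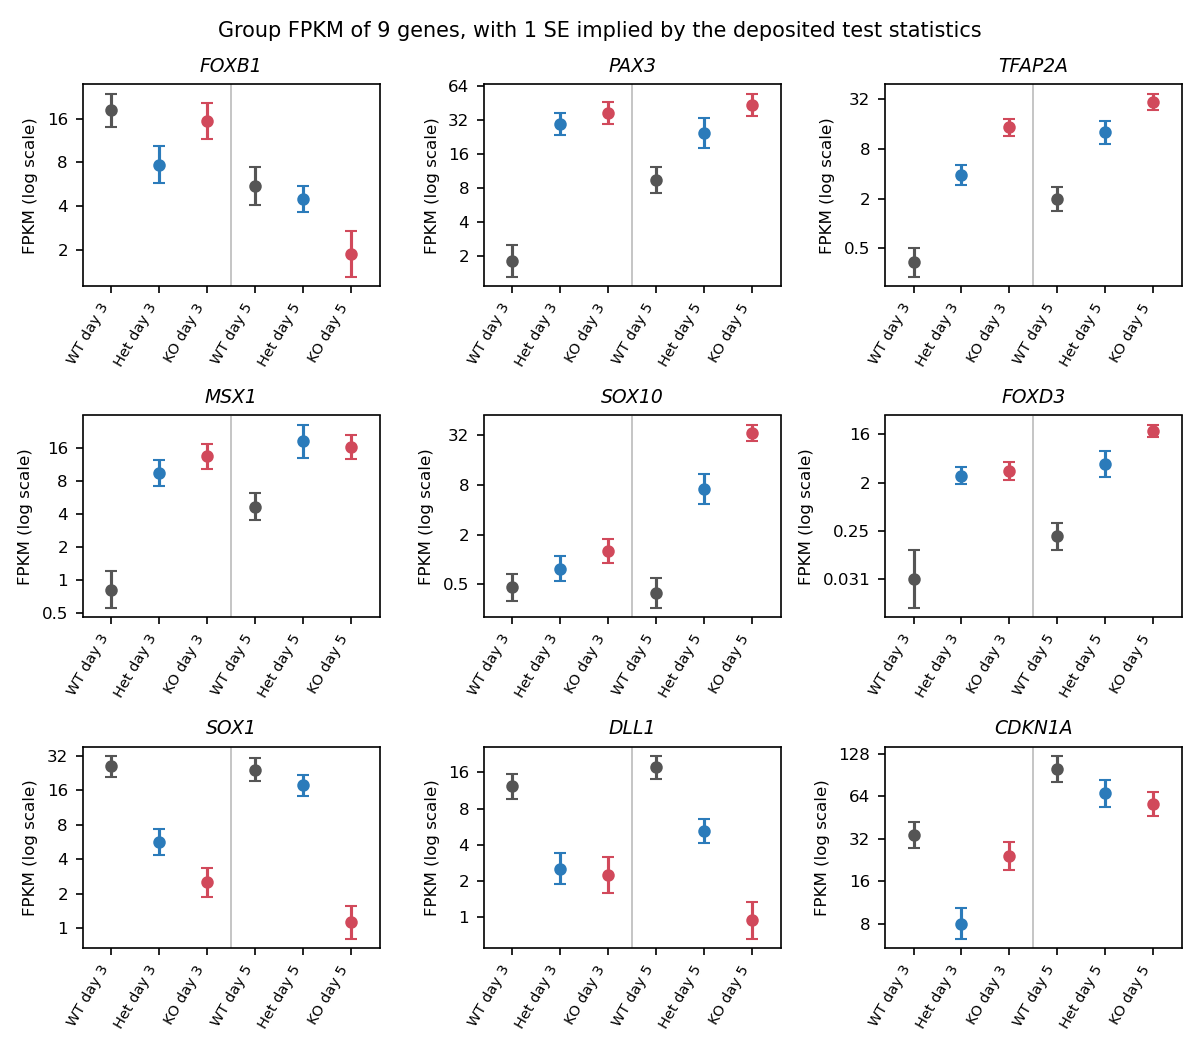
FPKM (log scale) of 9 genes in the 6 groups of the authors' deposited table, with bars of 1 implied SE either way. PAX3, TFAP2A and MSX1 were higher in both edited lines at each day, SOX10 and FOXD3 were highest in KO at day 5, and SOX1 and DLL1 were lower in both edited lines except that SOX1 was not called in Het at day 5.

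At day 3, the KO cells held more RNA of many neural plate border and BMP genes and of several WNT and FGF targets than wild type, and less of several neural progenitor genes. PAX3, a border and crest transcription factor, rose from 1.79 to 36.5 FPKM (log2 change 4.36, SE 0.57). BMP4, a secreted BMP ligand, rose from 0.153 to 9.55 FPKM (5.97, SE 1.14). SOX1, a neural progenitor factor, fell from 25.9 to 2.52 FPKM (-3.36, SE 0.52). Of 14678 genes tested in the authors' deposited table, 637 rose and 759 fell.

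The largest rise among genes at 1 FPKM or more was that of CER1, a secreted inhibitor of NODAL and BMP, from 0.206 to 17.5 FPKM (6.41, SE 1.01). It was followed by BMP4, TFAP2A (5.44, SE 0.68), the BMP inhibitor GREM1 (4.90, SE 0.54) and PAX7 (4.87, SE 0.61). MS4A6A, PCDH10, CALB1, LMX1A and TNIK rose by log2 changes of 4.83, 4.64, 4.54, 4.54 and 4.50. The largest fall was that of SFRP4, a secreted WNT modulator, from 10.9 to 0.116 FPKM (-6.56, SE 0.86). PKIB followed (-5.16, SE 0.59), then CES1, LOC100506013, PROC and VGLL2 at -4.60, -4.53, -4.07 and -3.93. DBX1, a homeobox gene of neural progenitors, EMP1, SERPINA1 and ZNF350 fell with log2 changes of -3.76, -3.74, -3.74 and -3.71.

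Among neural plate border genes, 9 of 15 tested rose and 1 fell at day 3 in KO in the authors' deposited table (11 and 2 adjusted over the list alone). The list median, over 18 members whether tested or not, was 1.49, above all 10000 lists drawn at random. The other list medians below likewise take in members that were not tested. MSX1 rose from 0.812 to 13.4 FPKM (4.04, SE 0.67). Of 19 neural crest specifiers, 5 rose and 1 fell in the authors' deposited table (8 and 2 adjusted over the list alone), with a median of 0.50 at percentile 99.98. TFAP2B, a crest transcription factor, rose from 0.135 to 1.32 FPKM (3.29, SE 0.75). For crest migration genes, 5 of 21 rose and 2 fell in the authors' deposited table (5 and 2 adjusted over the list alone), with a median of 0.28 at percentile 99.67. EDNRB, an endothelin receptor, rose (4.35, SE 0.93), as did the cadherin CDH6 (3.41, SE 0.49), while the guidance receptor NRP1 fell (-2.99, SE 0.63).

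Of 14 central neural progenitor genes, 3 rose and 6 fell in KO at day 3 in the authors' deposited table (4 and 8 adjusted over the list alone), with a median of -0.25 at percentile 2.14. SOX3 fell (-3.02, SE 0.63), and LHX5 rose (2.62, SE 0.62). In the midbrain and isthmus list, 5 of 11 rose and 1 fell in the authors' deposited table (6 and 2 adjusted over the list alone), with a median of 0.58, above all random draws. PAX2 rose from 1.27 to 10.6 FPKM (3.06, SE 0.59) and PAX5 from 0.104 to 0.818 FPKM (2.98, SE 0.96). Of 4 HOX genes tested, 1 rose and 0 fell in the authors' deposited table (3 and 1 adjusted over the list alone). The HOX median, over 10 members, was 0.58 at percentile 99.69. For neurogenic and sensory genes, 2 of 15 rose and 2 fell in the authors' deposited table (2 and 2 adjusted over the list alone), with a median of 0.02 at percentile 59.9. STMN2, a neuronal microtubule regulator, rose (2.64, SE 0.50). Of 15 Notch pathway genes, 1 rose and 2 fell in the authors' deposited table (3 and 3 adjusted over the list alone), with a median of -0.03 at percentile 47.9, or 0.21 at percentile 95.1 within GC bins. The ligand DLL1 fell from 12.3 to 2.24 FPKM (-2.45, SE 0.59), and HEY1 rose (2.03, SE 0.91).

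The BMP, WNT and FGF lists moved upward in KO at day 3. Of 19 BMP genes, 11 rose and 1 fell in the authors' deposited table (12 and 1 adjusted over the list alone), with a median of 1.47. BMP2 rose from 1.53 to 23.2 FPKM (3.92, SE 0.54). Of 22 WNT targets, 10 rose and 2 fell in the authors' deposited table (13 and 3 adjusted over the list alone), with a median of 0.93. DKK1, a secreted WNT inhibitor, rose (3.18, SE 0.72), as did BAMBI (3.39, SE 0.73), and NKD2 fell (-2.61, SE 0.96). Of 20 FGF and ERK targets, 8 rose and 2 fell in the authors' deposited table (9 and 2 adjusted over the list alone), with a median of 0.67. FGF19 rose from 1.32 to 19.1 FPKM (3.86, SE 0.65), and SPRY4, a feedback inhibitor of the pathway, rose (2.61, SE 0.54). All 3 medians lay above all random draws.

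Some genes of other fates and of pluripotency also rose in KO at day 3, while most tested members of these lists, the primitive streak list excepted, were not called. Of 18 pluripotency genes, 5 rose and 1 fell in the authors' deposited table (5 and 1 adjusted over the list alone), with a median of 0.56. TDGF1, a NODAL co-receptor, rose from 0.467 to 7.62 FPKM (4.03, SE 0.77), NODAL itself rose (3.02, SE 0.69) and NANOG rose from 1.03 to 6.76 FPKM (2.72, SE 0.64). Of 7 primitive streak, mesoderm and endoderm genes tested, 4 rose and 0 fell in the authors' deposited table (4 and 0 adjusted over the list alone). The list median was 1.34 over 24 members, most of them not tested. The VEGF receptor KDR rose (3.76, SE 0.53), as did T, the brachyury gene (2.47, SE 0.91). Of 16 placode and non-neural ectoderm genes, 5 rose and 0 fell in the authors' deposited table (5 and 1 adjusted over the list alone), with a median of 0.76. The epithelial cadherin CDH1 rose (2.96, SE 0.62). Of 14 mesenchyme and matrix genes, 5 rose and 0 fell in the authors' deposited table (6 and 1 adjusted over the list alone), with a median of 0.49, and PRRX1, a mesenchyme factor, rose from 0.258 to 1.19 FPKM. These 4 medians lay above all random draws.

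The other 6 lists held few calls in KO at day 3. For p53 targets 1 rose and 2 fell of 20 in the authors' deposited table (1 and 4 adjusted over the list alone), with a median of -0.33 at percentile 0.91. PMAIP1, a pro-apoptotic gene, rose (1.69, SE 0.62). For stress and hypoxia genes 1 rose and 3 fell of 19 in the authors' deposited table (1 and 5 adjusted over the list alone), with a median of -0.11 at percentile 23.8, and DDIT4 fell (-1.02, SE 0.42). For melanocyte and glia genes 1 rose and 1 fell of 8 in the authors' deposited table (1 and 1 adjusted over the list alone), with a median of -0.03 at percentile 46.3. For housekeeping genes 0 rose and 1 fell of 15 in the authors' deposited table (0 and 4 adjusted over the list alone), with a median of -0.14 at percentile 36.3, and the ribosomal gene RPLP0, on chromosome 12, fell (-0.83, SE 0.47). For the FOX family 1 rose and 0 fell of 12 in the authors' deposited table (1 and 1 adjusted over the list alone), with a median of 0.31 at percentile 99.2, or 0.18 at percentile 91.6 among members with at least 1 FPKM in a group, and the gene that rose was FOXH1. For proliferation genes 0 rose and 0 fell of 20 in the authors' deposited table (0 and 0 adjusted over the list alone), with a median of -0.06 at percentile 42.9.

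The log2 changes of KO at day 3 fell with transcript GC content (Spearman -0.44 across genes, which are not independent replicates). The median change was 0.17 in the lowest 20% of genes by GC content and -0.47 in the highest. With changes taken within GC bins and calls remade, 642 genes rose and 360 fell, beside 637 and 759 in the authors' deposited table. Within GC bins the central neural progenitor median was -0.16 at percentile 3.06, and the neurogenic and sensory median was 0.38 at percentile 99.9. Genes of chromosome 12 were lower in KO (median -0.47, 89.0% of 679 expressed genes below 0), and those of chromosome 1 beyond 125 Mb were higher (median 0.60, 576 genes). Among the genes named above, LMX1A and PRRX1 lie on chromosome 1 beyond 125 Mb, and EMP1, NANOG, LHX5 and RPLP0 on chromosome 12. From 140 Mb on, the 20 Mb windows of chromosome 1 had medians from 0.52 to 0.71 in KO against wild type. In KO against Het at day 3 they lay between 0.52 and 0.61. The windows up to 120 Mb lay between -0.27 and 0.23 against wild type and between -0.12 and 0.02 against Het. A copy number difference of the region beyond 125 Mb in KO would raise every part of it, as these medians did. No test was set for it, and line and genotype coincide here.

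In Het at day 3, several border, midbrain and BMP genes were again higher than in wild type, and many p53 targets and the neural progenitor genes SOX1 and SOX3 were lower. PAX3 rose from 1.79 to 29.3 FPKM (4.04, SE 0.57). OTX2, a forebrain and midbrain factor, rose from 11.0 to 41.5 FPKM (1.92, SE 0.49). CDKN1A, a p53 target that halts the cell cycle, fell from 34.1 to 8.03 FPKM (-2.08, SE 0.48). Of 14618 genes tested in the authors' deposited table, 245 rose and 677 fell.

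The largest rises in Het at day 3 were those of BMP4 (4.75, SE 1.15), GREM1 (4.73, SE 0.55), DNAJC15 (4.70, SE 0.64), OTX1 (4.21, SE 0.92) and ZFHX4 (4.20, SE 0.54). PAX7, PAX3, the WNT potentiator RSPO3, PCDH10 and LMX1A followed, with log2 changes from 4.15 to 3.88. The largest fall was that of FLG, filaggrin of the epidermis, from 4.63 to 0.019 FPKM (-7.93, SE 0.91). SCGB3A2 (-5.58), the chemokine CXCL11 (-5.05), SCG2 (-4.68), MB21D1 (-4.55) and S100A6 (-3.77) came next, then SMOC2, KCNJ8, KCNK12 and ZNF354C at -3.72, -3.63, -3.62 and -3.59.

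Of 15 neural plate border genes, 6 rose and 2 fell in Het at day 3 in the authors' deposited table (10 and 3 adjusted over the list alone), with a median of 0.96. MSX2 rose from 1.24 to 18.2 FPKM (3.87, SE 0.61). Of 19 crest specifiers, 6 rose and 0 fell in the authors' deposited table (6 and 0 adjusted over the list alone), with a median of 0.53. TFAP2A rose from 0.338 to 3.85 FPKM (3.51, SE 0.72). Of 11 midbrain and isthmus genes, 5 rose and 2 fell in the authors' deposited table (7 and 2 adjusted over the list alone), with a median of 1.31. EN1 rose (2.11, SE 0.59), and GBX2, which lies caudal to OTX2 in the embryo, fell (-2.82, SE 0.73). Of 19 BMP genes, 9 rose and 1 fell in the authors' deposited table (10 and 1 adjusted over the list alone), with a median of 0.82. These 4 medians lay above all random draws. Of 15 central neural progenitor genes, 4 rose and 4 fell in the authors' deposited table (4 and 6 adjusted over the list alone), with a median of 0.32 at percentile 99.98. SOX3 fell (-2.55, SE 0.58) and SOX1 fell from 25.9 to 5.63 FPKM (-2.20, SE 0.49).

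For WNT targets 6 of 20 rose and 2 fell in Het at day 3 in the authors' deposited table (9 and 4 adjusted over the list alone), with a median of 0.22 at percentile 99.4. WNT3A rose from 0.331 to 3.45 FPKM (3.38, SE 0.81), and WNT8A fell (-2.22, SE 0.63). For FGF and ERK targets 4 of 20 rose and 3 fell in the authors' deposited table (6 and 3 adjusted over the list alone), with a median of 0.25 at percentile 99.7. FGF19 rose (1.84, SE 0.70), and the receptor FGFR3 fell (-1.44, SE 0.42, or -0.93 within GC bins). For crest migration genes 4 of 21 rose and 2 fell in the authors' deposited table (5 and 2 adjusted over the list alone), with a median of 0.17 at percentile 98.0. CDH6 rose (3.25, SE 0.50), and the migration median was 0.11 at percentile 94.7 within GC bins and 0.01 at percentile 67.1 among members with at least 1 FPKM in a group. Of 12 mesenchyme and matrix genes, 4 rose and 1 fell in the authors' deposited table (4 and 1 adjusted over the list alone), with a median of 0.05 at percentile 77.0, or 0.24 at percentile 99.3 within GC bins. The contractile genes ACTA2 (2.37, SE 0.57) and TAGLN (1.56, SE 0.44) rose. Of 14 placode and non-neural ectoderm genes, 2 rose and 1 fell in the authors' deposited table (2 and 5 adjusted over the list alone), with a median of -0.15 at percentile 13.1, or -0.67 at percentile 1.92 among members with at least 1 FPKM in a group and 0.09 at percentile 70.7 within GC bins, and EYA4 rose (3.17, SE 0.75). Of the primitive streak, mesoderm and endoderm list 1 gene was tested, KDR, and it rose in the authors' deposited table (1 and 0 adjusted over the list alone), with a list median of 0.19 at percentile 98.3.

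Of 20 p53 targets, 0 rose and 11 fell in Het at day 3 in the authors' deposited table (0 and 16 adjusted over the list alone), with a median of -0.98, below all random draws, and of -0.91 within GC bins. PHLDA3 fell from 22.2 to 3.71 FPKM (-2.58, SE 0.56), and BBC3, a pro-apoptotic gene, fell (-1.93, SE 0.62, or -1.23 within GC bins). Of 15 Notch genes, 0 rose and 3 fell in the authors' deposited table (1 and 7 adjusted over the list alone), with a median of -0.45 at percentile 0.34. DLL1 fell (-2.27, SE 0.54), and within GC bins the Notch median was -0.07 at percentile 16.8. Of 14 pluripotency genes, 0 rose and 3 fell in the authors' deposited table (0 and 5 adjusted over the list alone), with a median of -0.36 at percentile 0.75, or -0.17 at percentile 3.01 with a pseudocount of 1. PRDM14 fell from 14.3 to 1.83 FPKM (-2.97, SE 0.58), and POU5F1 fell from 45.7 to 16.4 FPKM (-1.48, SE 0.50). The only HOX gene tested, HOXA2, fell in the authors' deposited table (-1.53, SE 0.75), which left 0 rises and 1 fall adjusted over the list alone, and the HOX median was -0.52 at percentile 0.07, or -1.44 at percentile 4.21 among members with at least 1 FPKM in a group. Of 12 neurogenic and sensory genes, 2 rose and 3 fell in the authors' deposited table (2 and 5 adjusted over the list alone), with a median of 0.02 at percentile 63.1, and POU4F1, a sensory neuron factor, rose (1.43, SE 0.51).

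Of 8 melanocyte and glia genes, 0 rose and 1 fell in Het at day 3 in the authors' deposited table (0 and 2 adjusted over the list alone), with a median of -0.15 at percentile 19.3, or -0.27 at percentile 0.83 within GC bins, and S100B fell (-1.74, SE 0.80). Of 19 stress and hypoxia genes, 0 rose and 3 fell in the authors' deposited table (0 and 3 adjusted over the list alone), with a median of -0.22 at percentile 8.55, and CHAC1 fell (-1.63, SE 0.61). Of 15 housekeeping genes, 0 rose and 2 fell in the authors' deposited table (0 and 3 adjusted over the list alone), with a median of -0.29 at percentile 20.8. They were GAPDH (-1.19, SE 0.54) and RPLP0 (-0.94, SE 0.46), both on chromosome 12. Of 12 FOX family genes, 0 rose and 3 fell in the authors' deposited table (0 and 3 adjusted over the list alone), with a median of 0.05 at percentile 72.5. They were FOXI3 (-2.33, SE 0.75), FOXB1 and FOXM1 (-0.83, SE 0.42), the last on chromosome 12. Of 20 proliferation genes, 0 rose and 0 fell in the authors' deposited table (0 and 0 adjusted over the list alone), with a median of 0.06 at percentile 92.9.

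The GC trend was steeper in Het at day 3 (Spearman -0.57 across genes). It stood also in the wild-type time course (-0.51), which uses the same wild-type day 3 group. Comparisons without that group ranged from -0.10 (KO against Het at day 5) to 0.41 (Het against wild type at day 5). KO against Het at day 3 had 0.05, and the time courses of Het and KO had 0.08 and -0.03. The negative trend thus went with the wild-type day 3 group. In Het at day 3 the median change was 0.21 in the lowest 20% of genes by GC content and -0.47 in the highest. With changes taken within GC bins and calls remade, 274 genes rose and 330 fell, beside 245 and 677 in the authors' deposited table. Chromosome 12 genes had a median of -0.52, with 90.2% of 682 expressed genes below 0, and chromosome 1 beyond 125 Mb had a median of 0.01. KCNJ8, named above as a fall, also lies on chromosome 12.

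**Figure D2:**
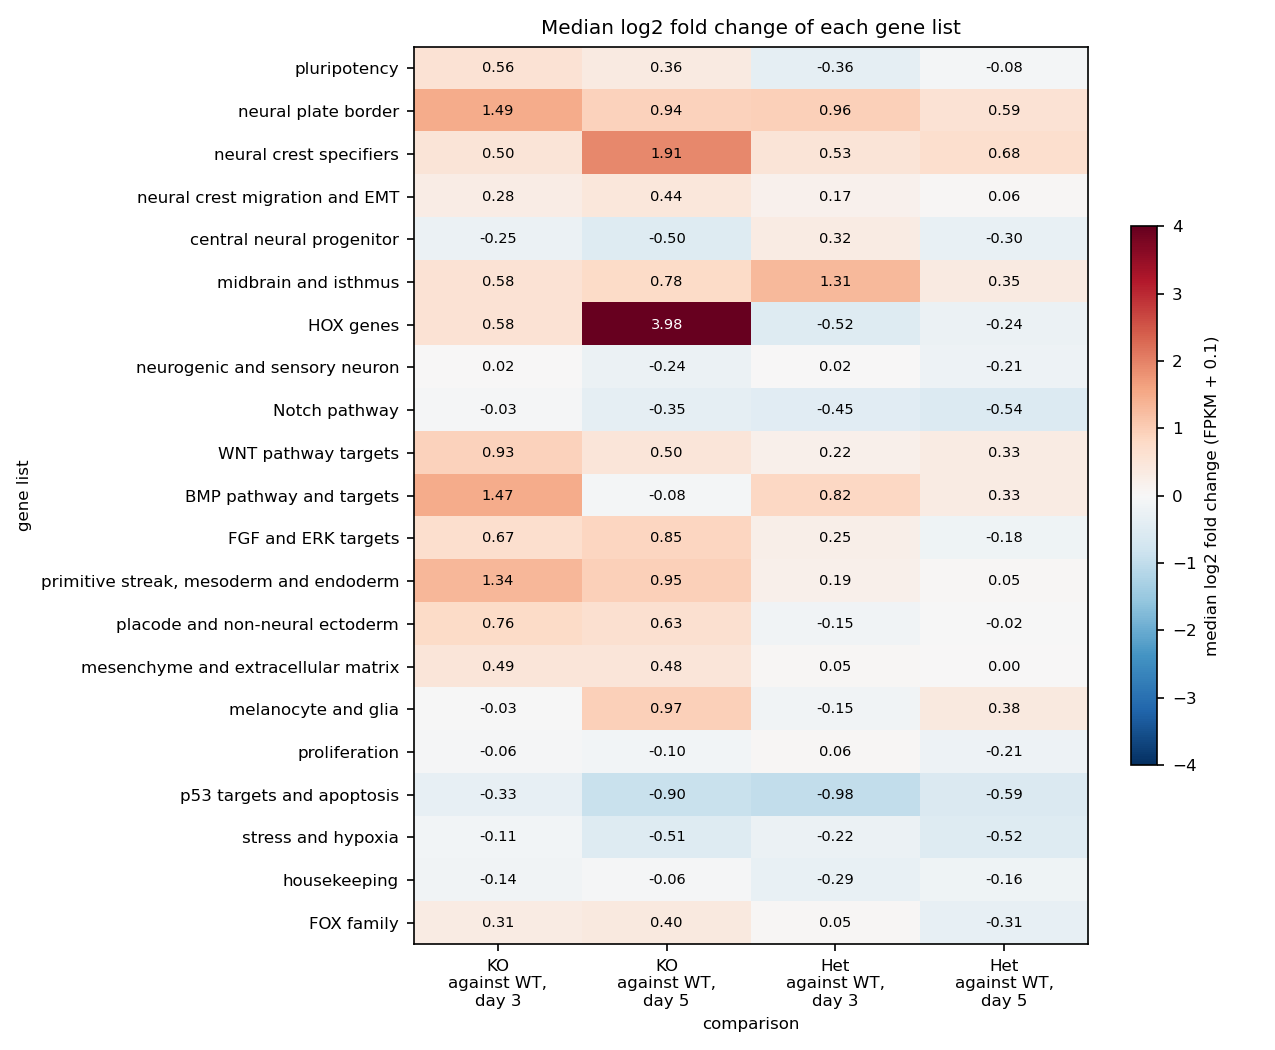
Median log2 change of each of the 21 gene lists (colour and printed value) in KO and Het against wild type at day 3 and day 5. Neural plate border and crest specifier medians were above 0 in all 4 comparisons, and these lists share PAX3, PAX7 and TFAP2A. The p53 target medians were below 0 in all 4.

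At day 5 the KO cells held more RNA of many neural crest specifiers and of several glial genes than wild type, and less of many neural progenitor genes and p53 targets and of several Notch pathway genes. SOX10, a crest and glial transcription factor, rose from 0.388 to 34.6 FPKM (6.48, SE 0.68). FOXD3, a crest factor, rose from 0.198 to 18.6 FPKM (6.56, SE 0.90). SOX1 fell from 24.2 to 1.13 FPKM (-4.43, SE 0.59), and DLL1 fell from 17.6 to 0.948 FPKM (-4.22, SE 0.61). Of 14936 genes tested in the authors' deposited table, 1132 rose and 849 fell.

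After FOXD3 and SOX10, the largest rises were those of S100B, a glial calcium-binding protein, from 1.64 to 125 FPKM (6.25, SE 0.83), DNAH9 (6.24, SE 0.98) and PRAME, from 0.751 to 55.7 FPKM (6.21, SE 0.86). ECSCR, ITGA8, RPH3A, OLIG2 and NFIX rose by log2 changes of 6.19, 6.14, 6.05, 6.02 and 5.99. SFRP4 fell the most, from 86.0 to 0.417 FPKM (-7.69, SE 0.64). FLG (-6.24, SE 0.82), PI15 (-6.08, SE 0.50), CXCL11 (-5.84, SE 1.01) and VGLL3 (-5.64, SE 0.44) followed. NTRK2, a neurotrophin receptor, LINC00052, the retinoic acid receptor RARB, CNTN3 and SYT10 fell with log2 changes of -5.61, -5.60, -5.30, -5.27 and -5.19.

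Of 19 crest specifiers, 11 rose and 1 fell in KO at day 5 in the authors' deposited table (11 and 2 adjusted over the list alone), with a median of 1.91. MYC rose from 7.46 to 208 FPKM (4.80, SE 0.53). Of 15 neural plate border genes, 8 rose and 2 fell in the authors' deposited table (8 and 3 adjusted over the list alone), with a median of 0.94. ZIC1 rose from 0.605 to 22.3 FPKM (5.20, SE 0.64), and TFAP2A rose (3.90, SE 0.59). Of 21 crest migration genes, 7 rose and 2 fell in the authors' deposited table (8 and 4 adjusted over the list alone), with a median of 0.44. EDNRA, an endothelin receptor of crest cells, rose from 3.31 to 49.5 FPKM (3.90, SE 0.51), and the cadherin CDH7 fell. Of 9 melanocyte and glia genes, 7 rose and 2 fell in the authors' deposited table (7 and 2 adjusted over the list alone), with a median of 0.97. ERBB3, a neuregulin receptor, rose (2.81, SE 0.83). Of 18 FGF and ERK targets, 8 rose and 3 fell in the authors' deposited table (10 and 4 adjusted over the list alone), with a median of 0.85. ETV4 rose (3.81, SE 0.63), as did DUSP4 (3.49, SE 0.55). These 5 medians lay above all random draws.

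HOX genes had a median of 3.98 in KO at day 5, above all random draws, and 3 of 9 rose and 1 fell in the authors' deposited table (5 and 1 adjusted over the list alone). HOXB2 rose from 0.211 to 8.60 FPKM (5.35, SE 1.00), and HOXA2 fell (-1.71, SE 0.59). The other rises called were HOXB1 and HOXA4, listed at 0 in wild type at day 5. HOXB3, HOXB4 and HOXA5, which were not called against wild type at day 5, stood in KO at day 3 at 4.72%, 3.80% and 2.95% of their KO day 5 level. In Het at day 5 HOXB3 stood at 0.77% of it, and the other 2 were listed at 0. These 5 genes were chosen after their values were seen. Of 17 FOX family genes, 6 rose and 3 fell in the authors' deposited table (6 and 3 adjusted over the list alone), with a median of 0.40 at percentile 94.2, or 0.57 at percentile 97.53 with a pseudocount of 0.01, and FOXD1 rose (3.80, SE 0.89). Of 9 midbrain and isthmus genes, 4 rose and 0 fell in the authors' deposited table (5 and 0 adjusted over the list alone), with a median of 0.78 at percentile 99.8, and LMX1B rose (1.89, SE 0.58). Of 20 WNT targets, 5 rose and 3 fell in the authors' deposited table (9 and 4 adjusted over the list alone), with a median of 0.50 at percentile 99.7, or 0.20 at percentile 96.7 with a pseudocount of 1. DKK1 rose (2.72, SE 0.88), and SP8 fell (-1.65, SE 0.56). Of 19 BMP genes, 6 rose and 2 fell in the authors' deposited table (7 and 5 adjusted over the list alone), with a median of -0.08 at percentile 25.8. BMP4 rose (3.32, SE 0.63), and the inhibitory SMAD6 fell (-2.12, SE 0.72). Of 16 placode and non-neural ectoderm genes, 7 rose and 0 fell in the authors' deposited table (7 and 0 adjusted over the list alone), with a median of 0.63 at percentile 99.9, and EYA4 rose (4.73, SE 0.69).

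Of 7 primitive streak, mesoderm and endoderm genes tested, 3 rose and 0 fell in KO at day 5 in the authors' deposited table (4 and 0 adjusted over the list alone). The list median was 0.95 at percentile 99.99 over 25 members, most of them not tested, and FOXC1 rose (4.33, SE 1.03). Of 17 mesenchyme and matrix genes, 5 rose and 3 fell in the authors' deposited table (6 and 3 adjusted over the list alone), with a median of 0.48 at percentile 99.8. TGFBI rose (3.97, SE 0.54), and TAGLN fell (-1.78, SE 0.55). Of 16 pluripotency genes, 3 rose and 4 fell in the authors' deposited table (4 and 5 adjusted over the list alone), with a median of 0.36 at percentile 96.2. POU5F1 rose from 3.61 to 8.56 FPKM (1.24, SE 0.62), and SOX2, shared with neural progenitors, fell from 140 to 58.0 FPKM (-1.27, SE 0.44).

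Of 15 central neural progenitor genes, 3 rose and 8 fell in KO at day 5 in the authors' deposited table (5 and 9 adjusted over the list alone), with a median of -0.50 at percentile 0.02, or -0.06 at percentile 8.05 with a pseudocount of 1. SOX21 fell (-4.28, SE 0.59). Of 18 neurogenic and sensory genes, 2 rose and 5 fell in the authors' deposited table (3 and 5 adjusted over the list alone), with a median of -0.24 at percentile 0.08. The neurofilament gene NEFM fell (-2.02, SE 0.53). Of 16 Notch genes, 1 rose and 6 fell in the authors' deposited table (1 and 7 adjusted over the list alone), with a median of -0.35 at percentile 0.49, and HES5, a Notch target, fell (-3.42, SE 0.94). Of 20 p53 targets, 0 rose and 14 fell in the authors' deposited table (0 and 15 adjusted over the list alone), with a median of -0.90, below all random draws. ZMAT3 fell (-1.39, SE 0.44), and RPS27L fell from 254 to 101 FPKM (-1.33, SE 0.43). Of 19 stress and hypoxia genes, 2 rose and 5 fell in the authors' deposited table (2 and 5 adjusted over the list alone), with a median of -0.51 at percentile 0.06. TRIB3 rose (3.46, SE 0.64), and the glucose transporter gene SLC2A1 fell (-1.53, SE 0.42). Of 20 proliferation genes, 0 rose and 2 fell in the authors' deposited table (0 and 4 adjusted over the list alone), with a median of -0.10 at percentile 59.6, and they were CCNB2 and CDK1 (-0.92, SE 0.43). Of 15 housekeeping genes, 2 rose and 1 fell in the authors' deposited table (2 and 1 adjusted over the list alone), with a median of -0.06 at percentile 83.9, and B2M rose (1.93, SE 0.49).

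Among the genes named for KO at day 5, S100B, PRAME, ECSCR, RPH3A, OLIG2 and MYC belonged to 35 genes with at least 5 FPKM there and under 0.05 of that level in both Het groups, a set chosen after the values were seen. HOXB3 belonged to it as well. Of the 35 genes, 21 were called in KO at day 5 in the authors' deposited table. The median level of the 35 genes, in percent of that in KO at day 5, was 5.63 in KO at day 3, 2.81 in wild type at day 3, 1.81 in wild type at day 5, 0.819 in Het at day 3 and 0.553 in Het at day 5. The Het values are low by the choice of the set. SOX10 stood at 20.5% of its KO day 5 level in Het at day 5, and FOXD3 at 24.1%. In KO at day 3, wild type at day 3 and wild type at day 5, SOX10 stood at 3.67%, 1.32% and 1.12%. FOXD3 stood there at 17.6%, 0.17% and 1.06%. Outside Het, SOX10 was thus as low as the 35 genes. In the authors' deposited table, 288 of the 1132 genes that rose in KO at day 5 also rose in KO at day 3 or in Het at day 5, and 287 of the 849 that fell did so there. Chromosome 12 genes had a median of -0.50, and those of chromosome 1 beyond 125 Mb a median of 0.37. SYT10, named above as a fall, lies on chromosome 12, as do RPH3A and ERBB3, named as rises.

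**Figure D3:**
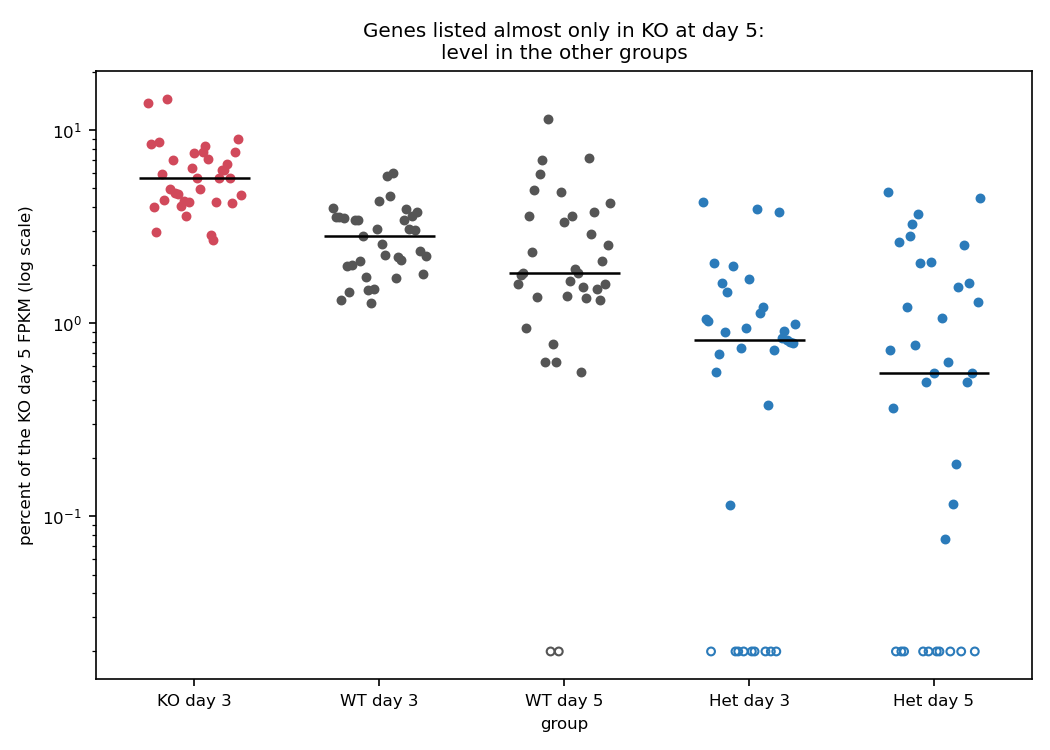
Level of each of 35 genes in 5 groups, in percent of its FPKM in KO at day 5 (log scale), with lines at group medians and open circles for genes listed at 0 or below the plotted range. The medians were 5.63 in KO at day 3 and 2.81 in wild type at day 3.

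In Het at day 5, many border genes and some crest and BMP genes were higher than in wild type, and a few Notch pathway, p53 and hypoxia genes were lower, while most members of the latter lists were not called. SOX10 rose from 0.388 to 7.07 FPKM (4.19, SE 0.85), and FOXD3 rose from 0.198 to 4.49 FPKM (4.50, SE 1.14). HES1, a Notch target, fell from 32.4 to 9.73 FPKM (-1.73, SE 0.56). Of 14561 genes tested in the authors' deposited table, 166 rose and 148 fell. With p-values adjusted within this comparison alone, 111 genes passed (64 rises and 47 falls).

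DNAJC15, a chaperone gene that was also among the largest rises in Het at day 3, rose the most in Het at day 5 (4.87, SE 0.81). FOXD3, KBTBD10, DKFZp686D0853, ITGA8, SOX10, SCRG1, LOC647946, PAX7 and PCDH10 followed, with log2 changes from 4.50 to 3.27. The falls were smaller, from HSPA6, a heat shock gene (-2.73, SE 0.87), and CTSF (-2.11, SE 0.82) to LOC339535 (-1.79, SE 0.71). EGR2, GRIN2B, HEY1, CYR61, ARC, STC1 and HSPA4L lay between them.

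Of 15 neural plate border genes, 8 rose and 0 fell in Het at day 5 in the authors' deposited table (8 and 0 adjusted over the list alone), with a median of 0.59. ZIC1 rose (3.09, SE 0.73). Of 19 crest specifiers, 7 rose and 2 fell in the authors' deposited table (10 and 2 adjusted over the list alone), with a median of 0.68, and TFAP2A rose (2.68, SE 0.67). Both medians lay above all random draws. Of 21 crest migration genes, 2 rose and 0 fell in the authors' deposited table (3 and 0 adjusted over the list alone), with a median of 0.06 at percentile 89.5, and they were EDNRA (2.48, SE 0.55) and CDH6 (2.23, SE 0.49). Of 8 melanocyte and glia genes, 1 rose and 0 fell in the authors' deposited table (3 and 0 adjusted over the list alone), with a median of 0.38, above all random draws. Of 19 BMP genes, 4 rose and 0 fell in the authors' deposited table (4 and 0 adjusted over the list alone), with a median of 0.33 at percentile 99.98, and MSX2 rose (2.17, SE 0.56). Of 8 midbrain and isthmus genes, 4 rose and 0 fell in the authors' deposited table (4 and 0 adjusted over the list alone), with a median of 0.35 at percentile 99.5, or 0.07 at percentile 92.8 with a pseudocount of 1, and WNT1 rose (1.21, SE 0.58). Of 20 WNT targets, 2 rose and 0 fell in the authors' deposited table (2 and 0 adjusted over the list alone), with a median of 0.33, above all random draws, and of 0.13 at percentile 89.7 within GC bins. WNT3A rose (1.75, SE 0.69).

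Of 16 Notch genes, 0 rose and 4 fell in Het at day 5 in the authors' deposited table (0 and 6 adjusted over the list alone), with a median of -0.54, below all random draws, and DLL1 fell (-1.75, SE 0.46). Of 20 p53 targets, 0 rose and 3 fell in the authors' deposited table (0 and 4 adjusted over the list alone), with a median of -0.59, below all random draws. They were ZMAT3 (-1.47, SE 0.48), MDM2 and SESN1 (-0.82, SE 0.47). Of 19 stress and hypoxia genes, 0 rose and 5 fell in the authors' deposited table (0 and 7 adjusted over the list alone), with a median of -0.52, below all random draws, and BNIP3 fell (-1.22, SE 0.42). Of 17 FGF and ERK targets, 1 rose and 3 fell in the authors' deposited table (1 and 4 adjusted over the list alone), with a median of -0.18 at percentile 4.66, and DUSP6 fell (-1.79, SE 0.48). Of 14 central neural progenitor genes, 2 rose and 1 fell in the authors' deposited table (3 and 1 adjusted over the list alone), with a median of -0.30 at percentile 0.04, and OTX1 rose (2.60, SE 1.07). Of 17 neurogenic and sensory genes, 0 rose and 2 fell in the authors' deposited table (0 and 2 adjusted over the list alone), with a median of -0.21 at percentile 0.29, and NEFL fell (-1.07, SE 0.57). Of 12 FOX family genes, 1 rose and 2 fell in the authors' deposited table (1 and 2 adjusted over the list alone), with a median of -0.31 at percentile 0.08, and FOXO1 fell (-1.19, SE 0.56).

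In the other 7 lists of Het at day 5 the authors' deposited table held 3 calls. KDR rose (2.01, SE 0.71), EYA4 rose (2.60, SE 0.73) and COL1A2 rose (0.87, SE 0.46), and adjusted over the list alone KDR and EYA4 stayed called. The medians were 0.05 for primitive streak, mesoderm and endoderm (1 gene tested, percentile 45.8), -0.02 for placode and non-neural ectoderm (12 tested, 33.2) and 0.00 for mesenchyme and matrix (15 tested, 44.8). They were -0.08 for pluripotency (15 tested, percentile 17.1), -0.24 for HOX genes (2 tested, 3.93), -0.21 for proliferation (20 tested, 0.97) and -0.16 for housekeeping genes (15 tested, 1.28). Among members with at least 1 FPKM in a group the pluripotency median was -0.30 at percentile 0.56 and the primitive streak, mesoderm and endoderm median 1.78 at percentile 97.55. With a pseudocount of 1 the HOX median was -0.09 at percentile 0.42, and with 0.01 it was -0.64 at percentile 1.53. Within GC bins the HOX median was -0.29 at percentile 1.51 and the housekeeping median -0.06 at percentile 4.18. The median of chromosome 12 genes was -0.27, and log2 changes rose with GC content (Spearman 0.41 across genes). GRIN2B, MDM2 and DUSP6, named as falls, lie on chromosome 12, as does WNT1, named as a rise.

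Because both edited lines were set against the same wild-type group, shared calls were counted with that in mind. At day 3, 181 genes rose and 368 fell in both KO and Het in the authors' deposited table, among them PAX3, PAX7, BMP4, GREM1, MSX1, LMX1A and CDH6, which rose, and SOX1, SOX3, DLL1 and NRP1, which fell. Among the 14395 genes tested in both, 558 rose in KO and 234 in Het and 759 and 677 fell, and independent lists of those sizes would share 9.07 rises and 35.7 falls, and 6 genes were called in opposite directions. At day 5, 124 rose and 92 fell in both in the authors' deposited table, among them SOX10, FOXD3, ZIC1, EDNRA and TFAP2A, which rose, and DLL1, SOX21 and ZMAT3, which fell. Among the 14328 genes tested in both, 893 rose in KO and 161 in Het and 849 and 148 fell, and independent lists would share 10.0 and 8.77, and 9 genes went opposite ways. Simulated unchanged groups against the same controls shared a mean of 4.66 calls at day 3 and 5.35 at day 5, with a highest count of 10 at each day. Neither the independent lists nor the simulation hold the GC trend of both lines at day 3 (Spearman -0.44 in KO and -0.57 in Het). The lower level of chromosome 12 genes in both lines is also left out of them. How many shared calls, falls above all, go with these was not counted.

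Across 11807 genes at day 3 the log2 changes of KO and Het had a covariance of 0.204 beside a simulated 0.0615. At day 5 it was 0.120 over 11919 genes beside 0.0729. Pearson's r across genes was 0.745 at day 3 and 0.473 at day 5, beside simulated values of 0.486 and 0.503. With all expressed genes (12306 and 12404) the covariance was 0.209 and 0.126 and the simulated one 0.918 and 1.37. The filters on small RNA features and on implied variance were applied together, so their parts in lowering the simulated values were not separated. KO and Het could not be set against separate control lines, so part of the excess may come from the shared wild-type group. The simulation held no GC trend and no chromosome 12 difference.

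Set against each other at day 3, KO held more RNA of several pluripotency genes and FGF targets than Het, and less of some neural progenitor genes. NANOG was at 6.76 FPKM in KO and 0.797 in Het (3.09, SE 0.66), and CDH1 at 7.83 and 0.442 (4.15, SE 0.61). OTX1 was at 0.451 FPKM in KO and 2.43 in Het (-2.43, SE 0.73). Of 14624 genes tested in the authors' deposited table, 337 were higher in KO and 79 lower. SCGB3A2 led the genes higher in KO (5.55, SE 1.00), before the chemokine CXCL12 (4.60, SE 1.87), SCNN1A, MPP1, ZNF354C and TRIML2 at 4.30, 4.27, 4.22 and 4.19. CDH1, the epithelial splicing factor gene ESRP1, PPP1R1B and ERVMER34-1 followed. SFRP4 led those lower in KO (-5.17, SE 0.88), followed by CES1 (-4.52), ZNF350 (-3.75), ZBTB16 (-3.37) and RWDD2B (-3.20). RSPO2, TNNI3, PI15, LOC100506013 and TRIM61 lay between -2.90 and -2.62.

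Of 18 pluripotency genes 9 were higher in KO and 0 lower at day 3 in the authors' deposited table (10 and 0 adjusted over the list alone). For FGF and ERK targets these were 6 and 0 of 20 in the authors' deposited table (6 and 0 adjusted over the list alone), and for central neural progenitor genes 0 and 4 of 14 (0 and 5). TDGF1 (3.84, SE 0.75), NODAL (3.07, SE 0.68) and PRDM14 (2.36, SE 0.58) were higher in KO than in Het. TFAP2A was higher (1.93, SE 0.53), as were EDNRB (3.00, SE 0.71), ETV4 (2.04, SE 0.58) and KDR (1.93, SE 0.48). The p53 targets CDKN1A (1.59, SE 0.49), PHLDA3 (1.60, SE 0.62) and BTG2 (1.37, SE 0.49) were higher in KO, and of the 20 members of that list 4 were higher and 0 lower in the authors' deposited table (7 and 0 adjusted over the list alone). PHLDA3 and BTG2 lie on chromosome 1 beyond 125 Mb. DBX1 (-2.38, SE 0.75), LIX1 (-1.86, SE 0.44), SOX1 (-1.16, SE 0.56) and WNT1 (-1.01, SE 0.47) were lower in KO. FOXB1 was not called (1.00, SE 0.59). The chromosome 12 median was 0.02, and that of chromosome 1 beyond 125 Mb was 0.57.

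At day 5, KO held more RNA of several crest specifiers, glial genes and FGF targets than Het and less of several neural progenitor genes. SOX10 was at 34.6 FPKM in KO and 7.07 in Het (2.29, SE 0.69), and SOX9, a crest and cartilage factor, at 28.0 and 6.62 (2.08, SE 0.56). SOX1 was at 1.13 and 17.7 FPKM (-3.97, SE 0.58). Of 15000 genes tested in the authors' deposited table, 833 were higher in KO and 376 lower. The 10 largest of the former were PRAME (9.06, SE 1.24), RPH3A (7.66, SE 0.78), SPARCL1, OAS3, CA12, HOXB3, NR3C1, SLC4A4, MYC and ECSCR, the last at 6.37, and 8 of them belong to the 35 genes above. The largest of the latter were SFRP4 (-7.24, SE 0.68), FLG (-6.36, SE 0.82), SYT10 (-4.91), PI15 (-4.71), VGLL3 (-4.50), TNNI3 (-4.46), RARB (-4.42), CXCL11 (-4.37), NTRK2 (-4.32) and LINC00052 (-4.25).

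Of 19 crest specifiers 8 were higher in KO and 1 lower at day 5 in the authors' deposited table (12 and 1 adjusted over the list alone). For FGF and ERK targets these were 10 and 1 of 18 in the authors' deposited table (12 and 1 adjusted over the list alone), for melanocyte and glia genes 5 and 1 of 9 (7 and 2) and for central neural progenitor genes 1 and 6 of 17 (3 and 8). FOXD3 (2.05, SE 0.88), ZIC1 (2.11, SE 0.57), EDNRA (1.42, SE 0.47) and ZEB1 (1.82, SE 0.49) were higher in KO than in Het. ETV5 (3.99, SE 0.58), DUSP4 (3.64, SE 0.56) and SPRY4 (3.04, SE 0.55) were higher, as were HOXB2 (4.26, SE 0.74), PRRX1 (4.34, SE 1.06), TGFBI (3.94, SE 0.54) and S100B (5.95, SE 0.72). SOX21 (-3.31, SE 0.59), LIX1 (-2.77, SE 0.49) and DLL1 (-2.47, SE 0.61) were lower in KO. HEY1 (2.90, SE 0.68) and HES1 (1.60, SE 0.55) were higher. FOXB1 was not called (-1.26, SE 0.60), the chromosome 12 median was -0.19, and that of chromosome 1 beyond 125 Mb, where PRRX1 lies, was 0.45.

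From day 3 to day 5 each genotype held less RNA of several pluripotency genes and more of several crest specifiers and matrix genes. POU5F1 fell from 45.7 to 3.61 FPKM in wild type (-3.66), and with log2 changes of -1.77 in Het and -2.98 in KO. TFAP2B rose by 3.63 in wild type, 3.63 in Het and 4.24 in KO, and COL1A2 rose by 2.47, 2.36 and 2.61. In the authors' deposited table, 1644 genes rose and 1531 fell in wild type, 702 and 418 in Het, and 1093 and 680 in KO. In it, 187 genes rose and 155 fell in all 3. The test passed smaller changes in wild type, where the ratio of test score to p-value was 0.55, beside 0.71 in Het and 0.72 in KO. With a log2 change of at least 1 the calls were 1995, 960 and 1634. The sizes of these counts, and of the list counts below, therefore cannot be compared between genotypes directly.

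Of 15 pluripotency genes tested in wild type, 1 rose and 9 fell with time in the authors' deposited table, beside 0 and 5 of 15 in Het and 0 and 13 of 18 in KO. L1TD1 and DNMT3B fell in all 3. Of 16 crest specifiers in wild type 9 rose and 0 fell in the authors' deposited table, beside 9 and 3 of 19 in Het and 14 and 1 of 19 in KO, where the median change was 2.09. ETS1, NR2F1 and NR2F2 rose in all 3. Of 19 BMP genes, 11 rose and 2 fell in wild type in the authors' deposited table, beside 3 and 2 in Het and 4 and 5 in KO. ID4 and BMP7 rose in all 3. Of 20 p53 targets, 9 rose and 0 fell in wild type in the authors' deposited table, beside 11 and 0 in Het and 3 and 1 in KO. CDKN1A rose by 1.56, 3.06 and 1.22. Mesenchyme and matrix genes had medians of 0.78, 0.72 and 0.96, above all random draws in wild type, Het and KO. The midbrain genes PAX2 and IRX1, the progenitor gene LHX5, the WNT target SP5 and FGF19 fell in all 3, and the receptor NGFR, CDH6, EDNRA, ZEB1, MAML2 and WNT3A rose. Among wild-type changes a GC trend was present (Spearman -0.51 across genes, beside 0.08 in Het and -0.03 in KO). Within GC bins calls remade in wild type came to 1103 rises and 914 falls.

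The change with time differed from that of wild type for 43 of 14104 genes in KO, 28 above wild type and 15 below, and for 13 of 14204 genes in Het, 9 above and 4 below. Small RNA features made up 3 of the 43 and 4 of the 9 above in Het, where 1 more of the 9 was outside the genes that could be named. In KO, S100B rose with time (4.14) while its log2 change in wild type was -1.20, a difference of 5.35 (SE 1.09). CA12 (4.54, SE 0.91), GABBR2 (4.96, SE 0.99), PDYN (5.11, SE 1.06), RWDD2B (4.91, SE 1.16) and the metallothionein gene MT2A (5.16, SE 1.27) also differed upward. S100B and CA12 belong to the 35 genes above. ANKRD1, a target of YAP, rose in wild type from 0.294 to 11.1 FPKM and stood at 0.875 and 0.799 in KO, a difference of -5.37 (SE 1.03). CAV1 (-4.18, SE 1.09), NXPH2 (-4.03, SE 0.92), ADCY2 (-3.84, SE 0.82), NTRK3 (-3.66, SE 0.91), NTRK2 (-3.51, SE 0.69), LRAT (-3.47, SE 0.91) and MAMDC2 (-3.08, SE 0.80) also differed downward in KO. In Het, ANKRD1 (-4.51, SE 1.00), PAPPA (-3.46, SE 0.78) and ANXA1 (-3.41, SE 0.82) differed downward. OLIG3, a dorsal neural tube factor, differed upward in KO (4.42, SE 1.01) and in Het. With SE scaled to the deposited p-values the counts were 727 in KO and 186 in Het, and with SE doubled they were 1 and 2. For the list medians of these differences, BMP genes had -1.95 in KO and -0.92 in Het, and melanocyte and glia genes had 2.46 and 0.64. Against wild type the BMP medians were already 1.47 in KO and 0.82 in Het at day 3. The timing differences were not adjusted for GC content, with which the wild-type changes fell (Spearman -0.51).

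**Figure D4:**
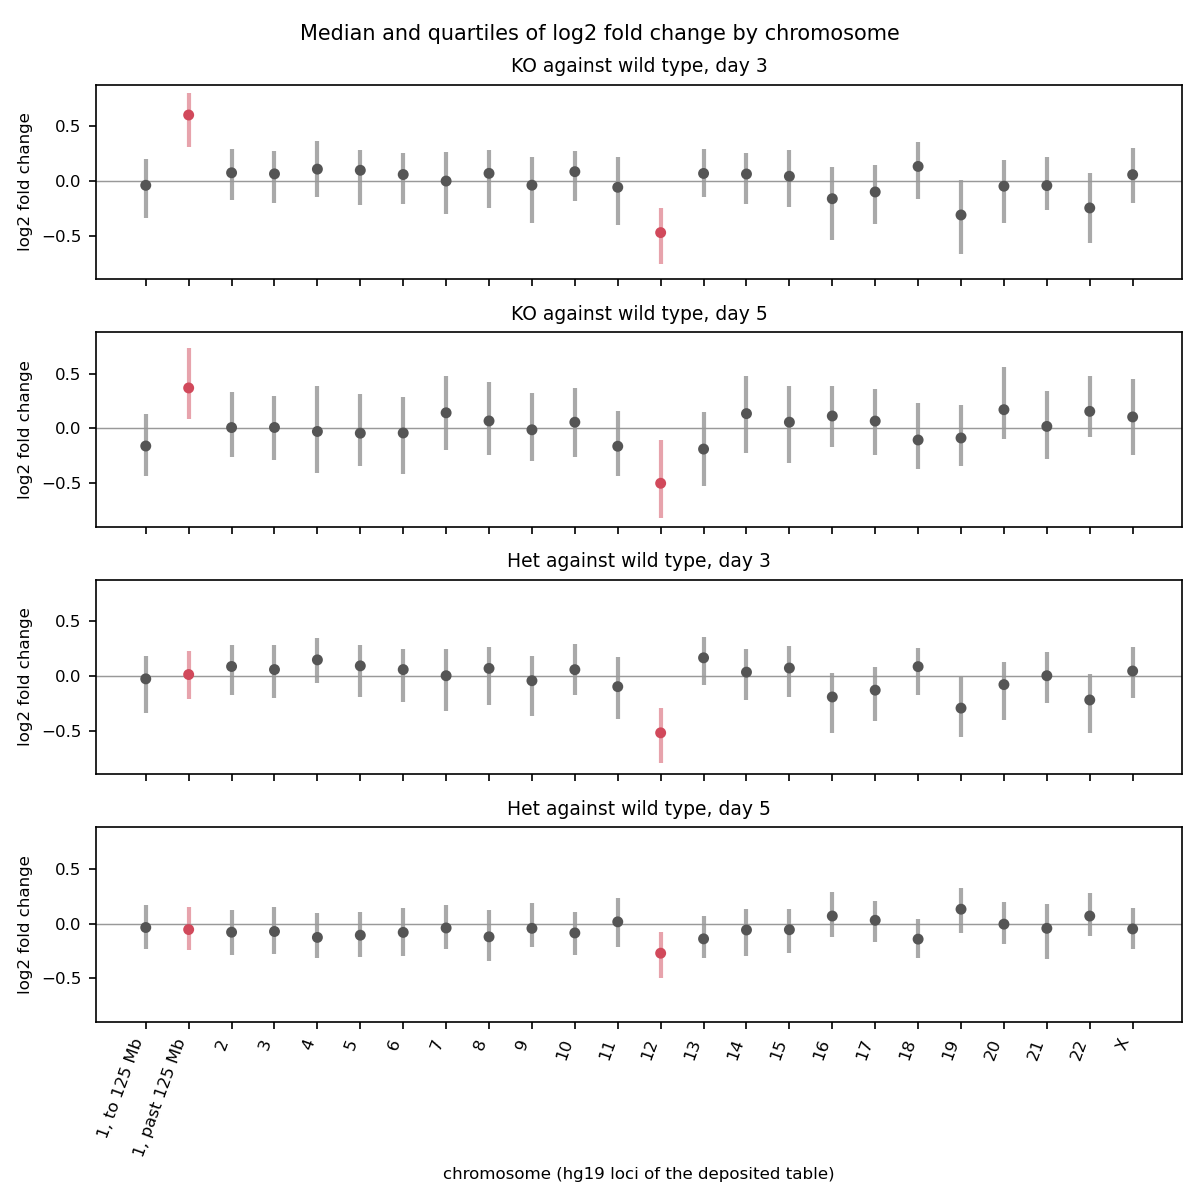
Median log2 change of expressed genes per chromosome (points) with quartiles (bars) in KO and Het against wild type at day 3 and day 5, with chromosome 1 divided at 125 Mb. Chromosome 12 was at -0.47 and -0.52 in KO and Het at day 3, and chromosome 1 beyond 125 Mb was at 0.60 in KO at day 3 and 0.01 in Het.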

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

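The tests of the 3 patterns weighed here were chosen after the patterns were seen, except the first test of GC content in Het at day 3. In KO, the change from day 3 to day 5 differed from that in wild type for 43 genes by a test of the difference itself. The largest differences were those of EDN1 (-7.49), DNAH9 (7.22), PAPPA (-5.77), ACSS1 (5.45) and SPARCL1 (5.42), the last of which belongs to the 35 genes weighed as the second pattern. In Het, 13 genes differed in that test, 4 of them small RNA features, and among those that could be named the largest differences were those of FLG (8.05), ZNF560 (7.04), SCGB3A2 (6.31), OLIG3 (5.58) and EDN1 (-5.52). EDN1 encodes endothelin 1, and in wild type it rose from 0.118 to 1.46 FPKM, while in KO it went from 1.87 to 0.127.

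The first pattern was the lower level of chromosome 12 genes in both edited lines, for which GC content alone would bring the median of KO at day 3 near 0 within GC bins, and it was -0.51 there. A copy number difference would lower every part of the chromosome, and in KO at day 3 the highest of the 7 window medians was -0.29, so that explanation stays open for KO. In Het the chromosome median went from -0.52 at day 3 to -0.27 at day 5, where the highest window median was -0.19. A difference that stayed the same in Het is counter to the change with time of these genes, which exceeded that in wild type by 0.298 within GC bins (SD over the other chromosomes 0.0418), beside 0.0222 in KO. Loss of FOXB1 could not be told apart from line, since line and genotype coincide in these samples. The median of KO against Het at day 3 was 0.0216, so the edited lines hardly differed there at that day. Both were compared with the same wild-type group, so a higher level of chromosome 12 genes in that group would give the same values. Which side differs was not tested.

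The second pattern was the 35 genes listed almost only in KO at day 5. RNA of another cell source would stand at 1 share of its KO day 5 level in KO at day 3, and the upper over lower quartile of that ratio was 1.71. Genes chosen in the same way at higher Het levels were about as narrow, at 1.97 for 39 genes (0.05 to 0.15 of the KO day 5 level in the higher Het group) and 1.82 for 91 genes (0.15 to 0.3), so this value did not decide, and the explanation stays open. An earlier test (94.3% of the genes higher in wild type than in Het at day 3) was set aside because the genes were chosen for low Het levels. Reads passed between libraries would list every gene in KO at day 3, where the lowest ratio to KO day 5 was 0.027, but it was 0.0587 among those 39 genes, so this did not decide either. A source with chromosome copy numbers of its own stayed open too (SD over chromosomes of the change with time 0.102 in KO, 0.0841 in Het and 0.0513 in wild type). The Het value holds its own shift of chromosome 12. Over the other chromosomes the SD of the difference from wild type was 0.106 in KO and 0.0418 in Het. That spread was larger in KO, as such a source would give, but nothing here ties it to the 35 genes. Loss of FOXB1 stayed open as well (median 5.63% of the KO day 5 level in KO at day 3), and these libraries cannot separate it from the other explanations.

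The third pattern was that more genes fell than rose in Het at day 3. The test written beforehand took the direction of 846 deposited calls within GC bins, and 71.9% lay below 0 both before and after. It decided little, since only 1 of these calls was no larger than the largest shift of a bin (0.69), beside a median size of 1.28. With calls remade within GC bins 54.6% of 604 calls lay below 0, beside 70.7% of 845 before and 66.7% of 798 after centring alone. GC content may therefore account for much of the excess of falls, and 464 of the 604 were deposited calls. The negative GC trend stood in the comparisons that used wild type at day 3, while KO against Het at day 3 had a Spearman value of 0.05. Whether the trend arose in the libraries or in the cells was not tested.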

How the results depend on the processing

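The settings chosen after the data were seen were GC bins, remade centred calls, the removal of chromosome regions or of the 35 genes, support from another group, and scaled SE. Of the counts and FOXB1 values, 80 stayed within 1.5 times their main value or kept their side of the threshold, and 23 moved. The balance of rises and falls turned in KO at day 3 from 637 and 759 to 642 and 360 within GC bins. In the wild-type time course it turned from 1644 and 1531 to 1385 and 1478 with calls remade after centring, and to 977 and 1018 with a log2 change of at least 1. Of the list medians under alternatives, 397 kept their side of the percentile bounds, 10 became more extreme and 13 less so, with no change of direction among those past the bounds. All 594 values of named genes kept their direction, which says little, since most of these genes were chosen as calls with large changes.

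With a q-value of 0.01, the calls came to 718 (KO day 3), 1203 (KO day 5), 452 (Het day 3), 136 (Het day 5), 200 and 691 (KO against Het, day 3 and day 5), and 2002, 520 and 1040 (time in wild type, Het and KO). Shared calls of KO and Het came to 266 at day 3 and 100 at day 5, and timing differences to 23 in KO and 7 in Het. All these are fewer because the threshold is stricter. Adjusted within the comparison alone, Het at day 5 had 111 calls and KO against Het at day 3 had 206. With a log2 change of at least 1 the wild-type time course had 1995. Within GC bins Het at day 3 had 604 and the wild-type time course 2017. Of the KO day 5 calls, 575 were also called in KO at day 3 or Het at day 5. Timing differences came to 727 in KO and 186 in Het with SE scaled, and to 1 and 2 with SE doubled.

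No paired analysis was possible because the labels share replicate numbers but the table holds no value per library. For the same reason leave-one-out, isoWT1 alone, isoWT2 alone, split controls and isoWT2 against isoWT1 could not be run, and outlying samples and other groupings of the samples were not examined. Depth is unknown, so no limit from it is given.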

Other observations

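The tests of this part were chosen after the values were seen. Crest factors stood at unlike shares of their KO day 5 level in the other groups. In Het at day 5 and KO at day 3, SOX10 stood at 20.5% and 3.67%, FOXD3 at 24.1% and 17.6%, TFAP2B at 42.0% and 5.30%, and PAX3 at 56.9% and 84.7%. HOXB3, S100B and MYC, members of the 35 genes, stood at 0.77%, 1.62% and 1.06% in Het at day 5. PRAME, a gene of the testis and of tumours, stood at 55.7 FPKM in KO at day 5 and at 2.35 in KO at day 3. MAGEA12 and CSAG1, of the same class, stood at 9.12 and 7.82 FPKM in KO at day 5. All 3 belong to the 35 genes, which were chosen for low Het levels.

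Chromosome 12 genes rose relative to other genes from day 3 to day 5 in Het (median 0.33, and 0.31 within GC bins), while the medians were 0.09 in wild type and 0.09 in KO. On chromosome 1 beyond 125 Mb, 122 of the 127 calls in KO at day 3 were rises, beside 4 of 12 in Het. A copy number difference of this region in KO was not tested.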
